A study of Oryza sativa with 12 samples.

How the data were processed

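Panicles of field-grown rice were sampled at lengths of 2 mm and 5-7 mm from the osmads1 mutant and wild type, with 3 biological replicates per group, per the labels. Total RNA was extracted with Trizol and labelled with the Affymetrix 3' IVT Express procedure, per the labels' protocols, which reads mainly the 3' part of a transcript. The deposited table holds log2 probe set levels, and Partek and RMA are named in the submitters' processing notes, with versions and settings not given in the sources used here. RMA subtracts background, quantile normalizes arrays and summarises probes on the log2 scale. It gives no detection call, so that no probe set was called absent and differences of dim probe sets are understated. Array medians of the deposited log2 values were 4.098 to 4.134 at 2 mm and 4.93 to 5.00 at 5-7 mm, and lower quartiles 3.008 to 3.046 and 3.515 to 3.591. The arrays of a length are thus nearly equal and the lengths differ, as if each had been normalized by itself, which the sources used here do not state. Genotype contrasts lie within a length. Interaction contrasts compare such differences, and contrasts between lengths would then mix stage with normalization.

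Replicate arrays correlated at 0.9954 to 0.9977 within groups across probe sets, and no pair was identical. Of the probe sets, 187 controls (64 reporter probe sets among them) were left out and 57194 were tested, with no filter. The platform annotation gave 1 gene symbol for 22436 of them, several for 95 and none for 34663. All 22436 matched the reference gene table (assembly ASM3414082v1), which gave current names and chromosomes. They cover 17905 genes, of which 2459 have an informative name, meaning a current symbol that is not a bare locus number or a synonym that is not a clone name. A gene was represented by its probe set with the highest mean over the 12 arrays.

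Tests used limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 arrays in 1 model, and eBayes (residual degrees of freedom 8, prior 4.74). Calls had a two-sided Benjamini-Hochberg adjusted p under 0.05 over all tested probe sets. Gene lists of at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 22 lists of a contrast, and again with an estimated correlation, under which no list passed. fry tests whether a list's genes move on balance one way and does not compare them with other genes. Controls were tested in a fit of their own. Figures were drawn with matplotlib 3.10.9. On simulated arrays with the 57194 probe sets, the 2 mm contrast recovered 56.7, 95.5 and 100 percent of changes of 0.5, 1 and 2 log2 units with 4 false calls. For the interaction these were 17.9, 71.6 and 100 percent with 5 false calls. With nothing changed at 5-7 mm there were 0 calls, and a list shifted by 0.5 at 5-7 mm was estimated at 0.535 with 0 other lists past the threshold. The simulated noise was independent between probe sets and few of them were changed, so these figures need not carry over to the real arrays.

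Groups, comparisons, tests, the lists' definitions and the alternatives were fixed before the data were examined. Lists cover the floral MADS-box classes and other MADS-box genes, spikelet and floral meristem, anther, meiosis, photosynthesis, auxin, cytokinin, gibberellin, jasmonate, secondary wall, YABBY, KNOX, SPL, ERF, lipid transfer and cuticle, cell cycle, histone, ribosomal protein and heat shock genes. The tables used hold no gene descriptions, so lists planned by description were built from gene names and synonyms before any test was run. As a result the histone list holds H2B genes alone, the ERF list mainly DREB genes and the secondary wall list also primary wall cellulose synthases. The photosynthesis list also holds LFNR1, PETE, petC and RCA. Names shared by several genes (OsIDS1, MFS1, RCN1, REP1, ASP1) were left out. SNB, APO1, TAW1, WUS, RCN2, RCN4, CYP704B2, DPW, MIL1, REC8, OsMADS31 and OsMADS32 were not matched by name. G1, LAX2, UDT1, PAIR3 and ZEP1 had no assigned probe set. Classes of under 5 measured genes have counts only.

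Named genes followed a rule fixed beforehand. It allows OsMADS1, the 6 largest rises and falls per genotype contrast among called genes whose replicates do not overlap, up to 4 members per list, and all floral MADS-box genes. For the interaction and stage contrasts it allows the 4 largest each way and up to 2 per list. The text names a subset of what the rule allows, and that subset was picked after the values were seen. LOC genes, control probe sets and the members of the 3 added lists (ABA and dehydration, clock, DNA replication) fall outside the rule and were also chosen after their values or those of related genes had been seen. Alternatives were quantile normalization or median centring of all arrays, 2 filters on dim probe sets, each comparison's own arrays, other variance priors, array weights, a replicate block, other thresholds, 1 probe set per gene, no shrinkage, leaving out each array, and other list tests.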

Results

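Transcript levels in young rice panicles were measured on Affymetrix rice arrays in the osmads1 mutant and in wild type, at panicle lengths of 2 mm and 5-7 mm. OsMADS1 encodes a MADS-box transcription factor of the SEPALLATA (E class) type that acts in floret meristem and floral organ identity. Inner floral organs begin to form in panicles of the shorter length, and organ development is advanced in the longer ones. Each of the 4 groups held 3 arrays from biological replicates, 12 arrays in all, and this number limits the precision. The study asked what OsMADS1 does early and late in flower development. Levels are log2 values given as mean ± SD (n = 3), differences are osmads1 minus wild type in log2 units ± SE, and adjusted p-values come from limma. The median level of an array was 4.098 to 4.134 at 2 mm and 4.93 to 5.00 at 5-7 mm, so that levels of the 2 lengths are not on one scale.

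The OsMADS1 transcript was far lower in the mutant at both lengths. The single OsMADS1 probe set, of a gene on chromosome 3, read 4.86 ± 0.52 in osmads1 and 10.80 ± 0.20 in wild type at 2 mm, 61.5-fold lower (-5.94 ± 0.31, adjusted p = 4.58e-08). At 5-7 mm it read 4.1 ± 0.76 and 11.53 ± 0.069, 173-fold lower (-7.43 ± 0.31, adjusted p = 3.48e-09). The 6 mutant arrays lay between 3.49 and 5.25 and the 6 wild-type arrays between 10.57 and 11.61. The mutant level stood at percentile 59.4 of all probe sets at 2 mm and 34.9 at 5-7 mm, and the labels do not give the allele or the genetic background of the mutant.

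At 2 mm, 4 MADS-box relatives of OsMADS1 fell in osmads1. OsMADS17 fell by 4.15-fold (-2.06 ± 0.13, adjusted p = 2.78e-07), and its fellow AGL6-type gene OsMADS6 differed by -1.88 ± 0.10, adjusted p = 6.43e-08. The E class genes OsMADS8 and OsMADS7 differed by -1.99 ± 0.16, adjusted p = 3.18e-06, and -1.98 ± 0.20, adjusted p = 2.96e-05. All 3 B class genes, which specify lodicules and stamens, were lower, with differences of -0.91 ± 0.18 for OsMADS16, -0.82 ± 0.15 for OsMADS4 and -0.46 ± 0.086 for OsMADS2. The C class gene OsMADS58 was lower as well (-1.32 ± 0.22, adjusted p = 0.00146).

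Other floral MADS-box genes did not pass the threshold at 2 mm. The A class genes OsMADS14, OsMADS15 and OsMADS18 had differences of 0.046, -0.062 and 0.17, and 0 of the 4 A class genes passed. The C class gene OsMADS3 (-0.42 ± 0.22, adjusted p = 0.282), the ovule gene OsMADS13 (-0.092, at levels of 2.73 and 2.82 near those of most reporter controls), OsMADS5 (0.14) and OsMADS34 (0.22) did not pass either, so that 1 of the 4 C and D class genes was lower. Of the 6 E class and AGL6 genes 0 were higher and 4 lower, or 0 and 4 adjusted over the list alone (mean -1.26, median -1.93, adjusted p = 0.0119). Of all 17 floral homeotic genes 0 were higher and 8 lower, or 0 and 8 adjusted over the list alone (mean -0.65, median -0.42, adjusted p = 0.0176). With an estimated correlation the adjusted p was 0.42 for both lists. Without osmads1 replicate 1 of this length that of the floral homeotic list was 0.0775 at the preset correlation. OsMADS50, a flowering activator of another MADS group, was slightly higher (0.30 ± 0.077, adjusted p = 0.0198). The OsMADS50 call was lost without any single 2 mm array other than osmads1 replicate 2 (adjusted p up to 0.0764, without osmads1 replicate 1).

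**Figure D1:**
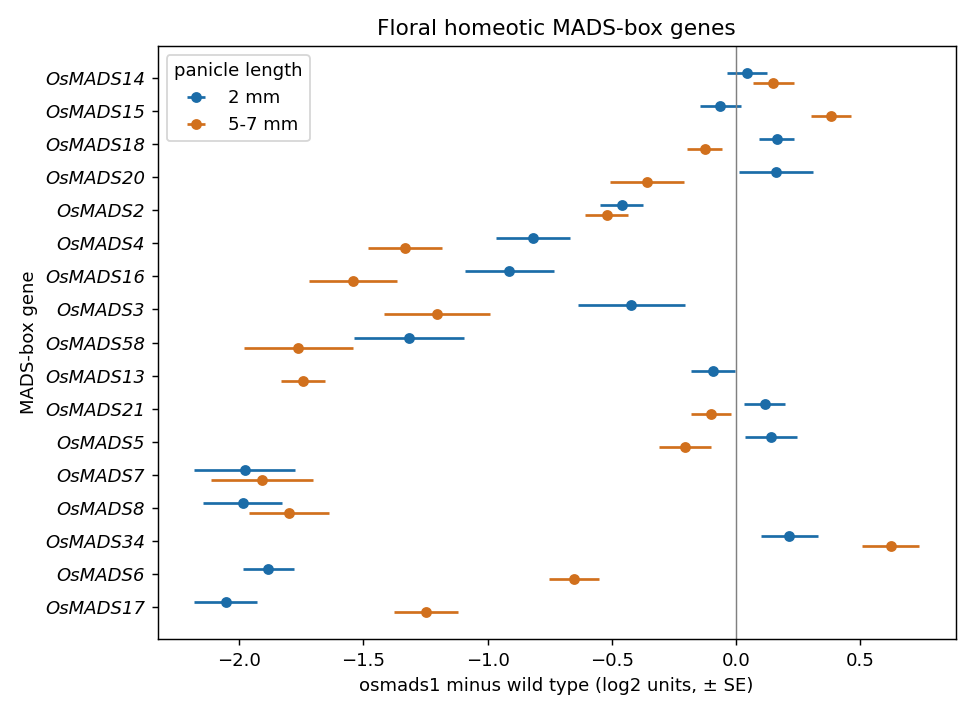
Differences of the 17 floral homeotic MADS-box genes between osmads1 and wild type, in log2 units with SE bars from limma, at 2 mm (blue) and 5-7 mm (orange), 3 arrays per group. OsMADS7 and OsMADS8 lie between -1.99 and -1.80 at both lengths, and OsMADS13 lies at -0.092 at 2 mm and -1.74 at 5-7 mm.

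At 2 mm, 4 of 10 anther genes and 5 of 13 photosynthesis genes rose in osmads1. OsC6, a tapetal lipid transfer protein, rose 6.62-fold (2.73 ± 0.086, adjusted p = 2.96e-10), and RAFTIN1 and CYP703A3, which act in making the pollen wall, rose 3.18-fold and at least 3.17-fold. CYP703A3 read 2.96 in wild type, below the upper quartile of reporter controls (3.26), so that its fold is a lower limit. MSP1, a receptor kinase that limits the number of sporogenous cells, fell (-0.60 ± 0.074, adjusted p = 0.000132). Of 10 anther genes 4 were higher and 1 lower, or 6 and 1 adjusted over the list alone (mean 0.64, median 0.26, adjusted p = 0.0171), with an adjusted p of 0.42 under an estimated correlation and of 0.188 among probe sets above the median level. The photosystem I gene PSAG (1.35 ± 0.096), the chlorophyll synthesis gene PORA (1.71 ± 0.19), the chlorophyll-binding protein gene RCABP89 (1.20 ± 0.19) and the cytochrome b6f gene petC (1.03 ± 0.15) rose. Of 13 photosynthesis genes 5 were higher and 0 lower, or 5 and 0 adjusted over the list alone (mean 0.54, median 0.34, adjusted p = 0.00714), with an adjusted p of 0.42 under an estimated correlation.

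At 2 mm, 23 of 58 cell cycle genes fell in osmads1. Of 58 cell cycle genes 1 was higher and 23 lower, or 1 and 27 adjusted over the list alone (mean -0.24, median -0.19, adjusted p = 1.51e-05, and adjusted p = 0.42 with an estimated correlation). The replication licensing genes OsMCM2 (-0.85 ± 0.091, adjusted p = 4.34e-05), OsMCM7 (-0.75) and OsMCM4 (-0.72) and the kinesin gene KIN8B (-0.50) fell. Of 5 histone H2B genes 0 were higher and 3 lower, or 0 and 5 adjusted over the list alone (mean -0.25, median -0.23, adjusted p = 0.0249, and adjusted p = 0.42 with an estimated correlation), H2B.10 at -0.30 ± 0.076, adjusted p = 0.0204. The H2B.10 call was lost without osmads1 replicate 2 or 3 or wild-type replicate 1 or 2 (adjusted p up to 0.0884). Of 37 jasmonate genes 5 were higher and 1 lower, or 5 and 1 adjusted over the list alone (mean 0.28, median 0.043, adjusted p = 0.0259, and adjusted p = 0.42 with an estimated correlation). Without osmads1 replicate 2 or wild-type replicate 1 the adjusted p of the jasmonate list was 0.0614 or 0.107. JAZ2, named for the repressors of jasmonate signalling, was at least 52.4-fold higher (5.71 ± 0.090, adjusted p = 5.13e-13), a lower limit since it read 2.44 in wild type, below the median of reporter controls (2.71), and JAZ7 rose by 0.73 ± 0.081.

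Among single genes with informative names, the clock gene OsCCA1 rose 12.9-fold and the clock gene OsPCL1 fell by 11.6-fold (differences of 3.69 ± 0.11 and -3.54 ± 0.11). OsC4 (15-fold), the zinc finger gene OsC3H40 (14.2-fold), the heat stress factor HSFC2A (10.3-fold) and the aquaporin gene OsNIP4;1 (at least 9.35-fold, from a wild-type level of 3.19 in the range of reporter controls) rose, and the kinase gene OsSAPK9 fell by 5.93-fold. In all, 6737 of 57194 probe sets passed an adjusted p of 0.05, 3144 higher and 3593 lower in osmads1, of which 531 and 244 changed at least 2-fold. Control readings also moved with genotype at this length, the 5' and middle GAPDH controls by 1.08 and 0.70, a cyclophilin control by 0.49 and the 25S rRNA control by -0.61 (adjusted p = 0.0107). The 3' minus 5' reading of a control transcript, a sign of RNA quality or labelling, was lower in osmads1 at 2 mm for GAPDH, 2.58 ± 0.059 against 3.58 ± 0.042 in wild type (SD, n = 3), and for 1 pair of probe sets each of actin, cyclophilin and ubiquitin, with the 3 osmads1 arrays below the 3 wild-type arrays. In another actin pair the arrays of the genotypes overlapped (5.63 ± 0.11 and 5.76 ± 0.19), as they did in a dim GAPDH pair (0.075 ± 0.21 and 0.17 ± 0.034).

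The remaining lists did not pass at 2 mm, although single members did. The KNOX genes OSH1 (-0.35) and OSH6 (-0.61), OsJAG (-0.55) and OsYABBY1 (-0.92) fell, and OsSPL14 rose (0.61 ± 0.091). The call of OSH1 was lost without wild-type replicate 1 (adjusted p = 0.0528), that of OsYABBY1 without wild-type replicate 2 (0.056) and that of OsJAG without osmads1 replicate 2 or 3 or wild-type replicate 2 or 3 (up to 0.129). Tested were the 9 spikelet and floral meristem genes (1 higher and 2 lower, 1 and 4 adjusted over the list alone, adjusted p = 0.342) and the 9 KNOX genes (1 higher and 3 lower, 1 and 3 adjusted over the list alone, adjusted p = 0.804). Tested too were the 6 YABBY genes (1 higher and 1 lower, 2 and 1 adjusted over the list alone, adjusted p = 0.373). Regulator lists held the 11 SPL genes (4 higher and 0 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.121), the 10 ERF genes (0 higher and 1 lower, 0 and 1 adjusted over the list alone, adjusted p = 0.506), and the 8 other MIKC-type MADS genes (1 higher and 0 lower, 2 and 0 adjusted over the list alone, adjusted p = 0.169). All 30 named MADS-box genes were tested together, of which 2 were higher and 8 lower, or 3 and 8 adjusted over the list alone, with a mean of -0.29, a median of 0.0069 and an adjusted p of 0.471. Also tested were the 7 meiosis genes (1 higher and 4 lower, 1 and 5 adjusted over the list alone, adjusted p = 0.0987), in which CRC1 differed by -0.77 ± 0.10. Hormone lists held the 60 auxin genes (6 higher and 9 lower, 6 and 9 adjusted over the list alone, adjusted p = 0.907), the 32 cytokinin genes (5 higher and 6 lower, 6 and 7 adjusted over the list alone, adjusted p = 0.79), and the 11 gibberellin genes (0 higher and 0 lower, 0 and 0 adjusted over the list alone, adjusted p = 0.169). The auxin mean (-0.022) had the opposite sign to its median and test, and the mean and median of the named MADS-box genes differed in sign. Other lists held the 32 secondary wall genes (1 higher and 2 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.804), the 6 lipid transfer and cuticle genes (2 higher and 0 lower, 3 and 0 adjusted over the list alone, adjusted p = 0.136), and the 24 ribosomal protein genes (0 higher and 0 lower, 0 and 0 adjusted over the list alone, adjusted p = 0.136). In the heat shock list HSP18.6 (-1.003) and HSFB2C (-1.49) fell and HSP17.9A (0.90) rose, among the 42 heat shock genes (7 higher and 12 lower, 9 and 12 adjusted over the list alone, adjusted p = 0.471). LTP110-A, a lipid transfer protein gene, rose by 0.98 ± 0.075.

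At 5-7 mm, 10 of the 17 floral homeotic MADS-box genes fell in osmads1 and 2 rose. OsMADS7 and OsMADS8 differed by -1.91 ± 0.20 and -1.80 ± 0.16, OsMADS17 by -1.25 ± 0.13 and OsMADS6 by -0.65 ± 0.10. OsMADS13 fell by at least 3.35-fold (-1.74 ± 0.089, adjusted p = 2.04e-08, to 3.56, in the range of reporter controls), OsMADS58 by 3.39-fold and OsMADS3 by 2.3-fold. The change of the OsMADS3 difference from 2 mm did not pass (interaction -0.78 ± 0.30, adjusted p = 0.0881, and 0.0263 without osmads1 replicate 3 of this length). The B class genes OsMADS16, OsMADS4 and OsMADS2 differed by -1.54, -1.33 and -0.52. OsMADS34, which promotes spikelet meristem identity, was higher (0.62 ± 0.12, adjusted p = 0.00151), as were OsMADS15 (0.38 ± 0.081, adjusted p = 0.00415) and OsMADS50 (0.72 ± 0.077).

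Of the 17 floral homeotic genes 2 were higher and 10 lower, or 2 and 11 adjusted over the list alone at 5-7 mm (mean -0.78, median -0.65, adjusted p = 0.00787), with an adjusted p of 0.822 under an estimated correlation and of 0.0936 among probe sets above the median level. Of the 6 E class and AGL6 genes 1 was higher and 4 lower, or 1 and 4 adjusted over the list alone, and they did not pass as a list (adjusted p = 0.113, and 0.489 for the interaction). Lower were 3 of 3 B class and 3 of 4 C and D class genes, and 1 of 4 A class genes was higher. OsMADS14 (0.15), OsMADS18 (-0.13) and OsMADS5 (-0.21) did not pass. OsMADS22, of the SVP group, fell by 1.82-fold (-0.87 ± 0.16, adjusted p = 0.00178).

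Some meristem genes rose and others fell in osmads1 at 5-7 mm, and of 58 cell cycle genes 16 rose and 3 fell. With 1 probe set per gene, a larger share of all genes than of this list was called at this length. The number called thus does not set the list apart. LAX1, a regulator of axillary meristem formation, rose 5.23-fold (2.39 ± 0.14, adjusted p = 9.96e-08), and RFL, the rice LEAFY gene, rose 2.39-fold (1.26 ± 0.12, adjusted p = 5.85e-06). The KNOX homeobox genes OSH71, OSH6 and OSH3 rose by 0.95 ± 0.076, 0.93 ± 0.084 and 0.53 ± 0.083. LOG (-1.01 ± 0.14, adjusted p = 0.000136), which activates cytokinin, and the organ growth genes OsJAG (-1.14 ± 0.15) and OsYABBY1 (-1.16 ± 0.21) fell. Of 58 cell cycle genes 16 were higher and 3 lower, or 17 and 4 adjusted over the list alone (mean 0.19, median 0.081, adjusted p = 0.0222, and adjusted p = 0.827 with an estimated correlation). OsMCM7, OsMCM6, OsMCM4 and OsMCM2 rose by 1.38, 1.20, 1.17 and 0.96. Without wild-type replicate 1 of this length the cell cycle list had an adjusted p of 0.0518.

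The largest named rises at 5-7 mm were JAZ2 (at least 148-fold, 7.21 ± 0.090, adjusted p = 1.60e-14), the late embryogenesis gene EM (13.5-fold), cob (7.48-fold), the sugar transporter gene OsSWEET15 (6.31-fold) and the chlorophyll-binding protein gene CAB2R (5.64-fold). The largest named falls other than OsMADS1 were the stress-related transcription factor gene OsWRKY71 (19.8-fold, -4.31 ± 0.28, adjusted p = 2.11e-07), the COBRA-like gene BC1L9 (15.6-fold), the amylase gene AMY1.3 (at least 12.1-fold), the zinc finger gene OsC3H37 (10.2-fold) and the stress NAC gene OsNAC6 (10.2-fold). The JAZ2 level in wild type (2.58) and the AMY1.3 level in osmads1 (3.24) lay in the range of reporter controls, so that these folds are lower limits. AMY1.3 fell by 7.86-fold without wild-type replicate 1 of this length and by 19.9-fold without wild-type replicate 2. DREB1A, a cold and drought regulator, fell by 4.21-fold. In all, 12285 probe sets passed, 5831 higher and 6454 lower in osmads1, of which 998 and 956 changed at least 2-fold. Control readings moved with genotype at this length too. Of the 9 thr controls, for a Bacillus transcript, 5 were lower in osmads1, from -1.51 for AFFX-r2-Bs-thr-5_s_at (adjusted p = 1.15e-05) to -0.52 for AFFX-ThrX-5_at (adjusted p = 0.00778). An actin control (0.35) and 2 cyclophilin controls (0.46 and 0.43) were higher, and a reporter control was lower (-0.47).

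The remaining lists did not pass at 5-7 mm, although single members did. In the anther list, TIP2, a tapetal regulator, fell by 3.83-fold (-1.94 ± 0.17, adjusted p = 3.14e-06) and TDL1A, a ligand of MSP1, by 1.72-fold. Reproductive lists held the 10 anther genes (1 higher and 2 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.635), and the 7 meiosis genes (1 higher and 2 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.701), in which MEL1 differed by -0.76 ± 0.13. Of the 13 photosynthesis genes (4 higher and 1 lower, 5 and 1 adjusted over the list alone, adjusted p = 0.147), RCABP69 differed by 2.18 and LFNR1 by 0.80, and without osmads1 replicate 2 the list's adjusted p was 0.0381. Auxin genes included the efflux carrier PIN3A (-1.45 ± 0.10) and OsETTIN1 (0.77 ± 0.074). Gibberellin genes included the deactivating enzyme EUI1 (-1.14 ± 0.083) and the receptor GID1 (-0.63 ± 0.084). JAZ8 rose by 1.16 and JAZ10 differed by -1.504. Hormone lists held the 60 auxin genes (15 higher and 10 lower, 18 and 14 adjusted over the list alone, adjusted p = 0.191), the 32 cytokinin genes (6 higher and 8 lower, 6 and 9 adjusted over the list alone, adjusted p = 0.924) and the 11 gibberellin genes (2 higher and 4 lower, 2 and 5 adjusted over the list alone, adjusted p = 0.351). They also held the 37 jasmonate genes (7 higher and 8 lower, 9 and 8 adjusted over the list alone, adjusted p = 0.559). Development lists held the 9 spikelet and floral meristem genes (4 higher and 4 lower, 4 and 5 adjusted over the list alone, adjusted p = 0.793), the 9 KNOX genes (4 higher and 1 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.23), and the 6 YABBY genes (0 higher and 1 lower, 0 and 1 adjusted over the list alone, adjusted p = 0.924). Regulator lists held the 11 SPL genes (2 higher and 4 lower, 2 and 5 adjusted over the list alone, adjusted p = 0.481) and the 10 ERF genes (1 higher and 3 lower, 1 and 3 adjusted over the list alone, adjusted p = 0.849). MADS-box lists held the 8 other MIKC-type MADS genes (1 higher and 1 lower, 1 and 1 adjusted over the list alone, adjusted p = 0.641), and the 30 named MADS-box genes (3 higher and 12 lower, 3 and 12 adjusted over the list alone, adjusted p = 0.153). Other lists held the 32 secondary wall genes (3 higher and 3 lower, 3 and 3 adjusted over the list alone, adjusted p = 0.775) and the 6 lipid transfer and cuticle genes (2 higher and 3 lower, 2 and 3 adjusted over the list alone, adjusted p = 0.924). Basic functions were covered by the 5 histone genes (2 higher and 0 lower, 3 and 0 adjusted over the list alone, adjusted p = 0.134), the 24 ribosomal protein genes (2 higher and 1 lower, 2 and 1 adjusted over the list alone, adjusted p = 0.182), and the 42 heat shock genes (8 higher and 5 lower, 8 and 6 adjusted over the list alone, adjusted p = 0.591). In the meristem, KNOX, YABBY, ERF and secondary wall lists the mean and the median or test differed in sign, as they did for cytokinin and lipid transfer. OsLG1, an SPL gene, rose by 1.34 ± 0.10 and LTP110-A by 1.08 ± 0.075.

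**Figure D2:**
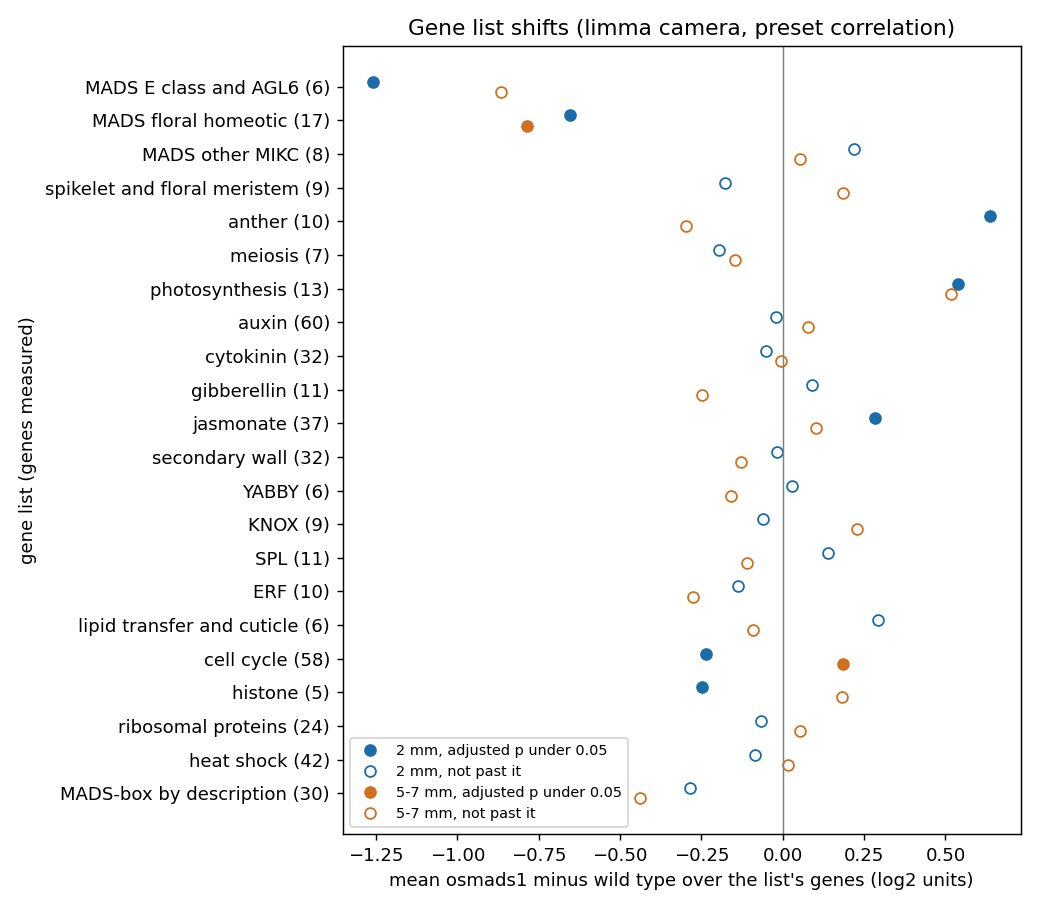
Mean difference between osmads1 and wild type over the genes of each tested list, in log2 units, at 2 mm (blue) and 5-7 mm (orange), with filled points where limma's camera test gave an adjusted p under 0.05 at its preset correlation. The cell cycle list lies at -0.24 at 2 mm and 0.19 at 5-7 mm, and the floral homeotic list lies below 0 at both.

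The genotype difference itself changed between the 2 lengths for many genes, tested as an interaction. The dehydration genes RAB16B and RAB21 were 6.33-fold and 6.43-fold higher in osmads1 at 2 mm and at least 7.17-fold and 4.55-fold lower at 5-7 mm (interactions of -5.50 ± 0.43, adjusted p = 1.03e-06, and -4.87 ± 0.51, adjusted p = 1.47e-05). Without osmads1 replicate 1 of 2 mm RAB21 was 9.67-fold higher there and its interaction was -5.46. At 5-7 mm RAB16B read 3.65 in osmads1, in the range of reporter controls. OsC3H37 and OsC3H40 were also higher in osmads1 at 2 mm and lower at 5-7 mm (interactions of -5.07 ± 0.18 and -4.94 ± 0.14). cob, OsPCL1, OsSWEET15 and EM had the largest positive interactions among named genes, 3.57, 3.57, 3.54 and 3.32. LAX1 went from -0.46 (adjusted p = 0.0546, and 0.0205 without wild-type replicate 3 of 5-7 mm) to 2.39 (interaction 2.85 ± 0.20, adjusted p = 4.52e-07), OSH6 from -0.61 to 0.93 and RFL from -0.025 to 1.26.

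The cell cycle list had the clearest interaction, where of 58 genes 26 were positive and 4 negative, or 28 and 5 adjusted over the list alone (mean 0.42, median 0.28, adjusted p = 9.47e-05), OsMCM7 at 2.12 ± 0.15, adjusted p = 4.01e-07 and OsMCM4 at 1.89 ± 0.13. All 5 histone genes had a positive interaction past the threshold (mean 0.43, adjusted p = 0.0314), H2B.10 at 0.57 ± 0.11. The anther list moved the other way, where of 10 genes 1 was positive and 7 negative, or 1 and 8 adjusted over the list alone (mean -0.93, median -0.66, adjusted p = 0.0314), OsC6 at -2.70 ± 0.12 and RAFTIN1 at -1.80 ± 0.20. With an estimated correlation the adjusted p of all 3 lists was 0.874. Among probe sets above the lowest quartile of level the adjusted p was 0.0559 for anther and 0.0559 for histone. Among those above the median level it was 0.168 and 0.0686, and after centring arrays on their medians that for histone was 0.0508. Among the floral MADS-box genes, OsMADS6 (1.23 ± 0.15, adjusted p = 3.92e-05) and OsMADS17 (0.81 ± 0.18, adjusted p = 0.00563) were less reduced at 5-7 mm. OsMADS13 also had an interaction (-1.65 ± 0.13, adjusted p = 8.44e-07), but at 2 mm it read 2.73 in osmads1 and 2.82 in wild type, too low for a fall to be seen there. The other 19 tested lists did not pass, with adjusted p from 0.0915 for ribosomal proteins (0.048 without osmads1 replicate 1 at 2 mm) to 0.916 for ERF, photosynthesis at 0.732 and jasmonate at 0.714 among them. In the meristem, KNOX, secondary wall and ERF lists the mean, the median or the test of the interaction differed in sign. Interaction calls numbered 12750 probe sets, 6487 positive and 6263 negative. The reporter control probe set RPTR-Os-K01193-1_at, outside these counts, had an interaction of -3.69, being higher in osmads1 at 2 mm alone.

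**Figure D3:**
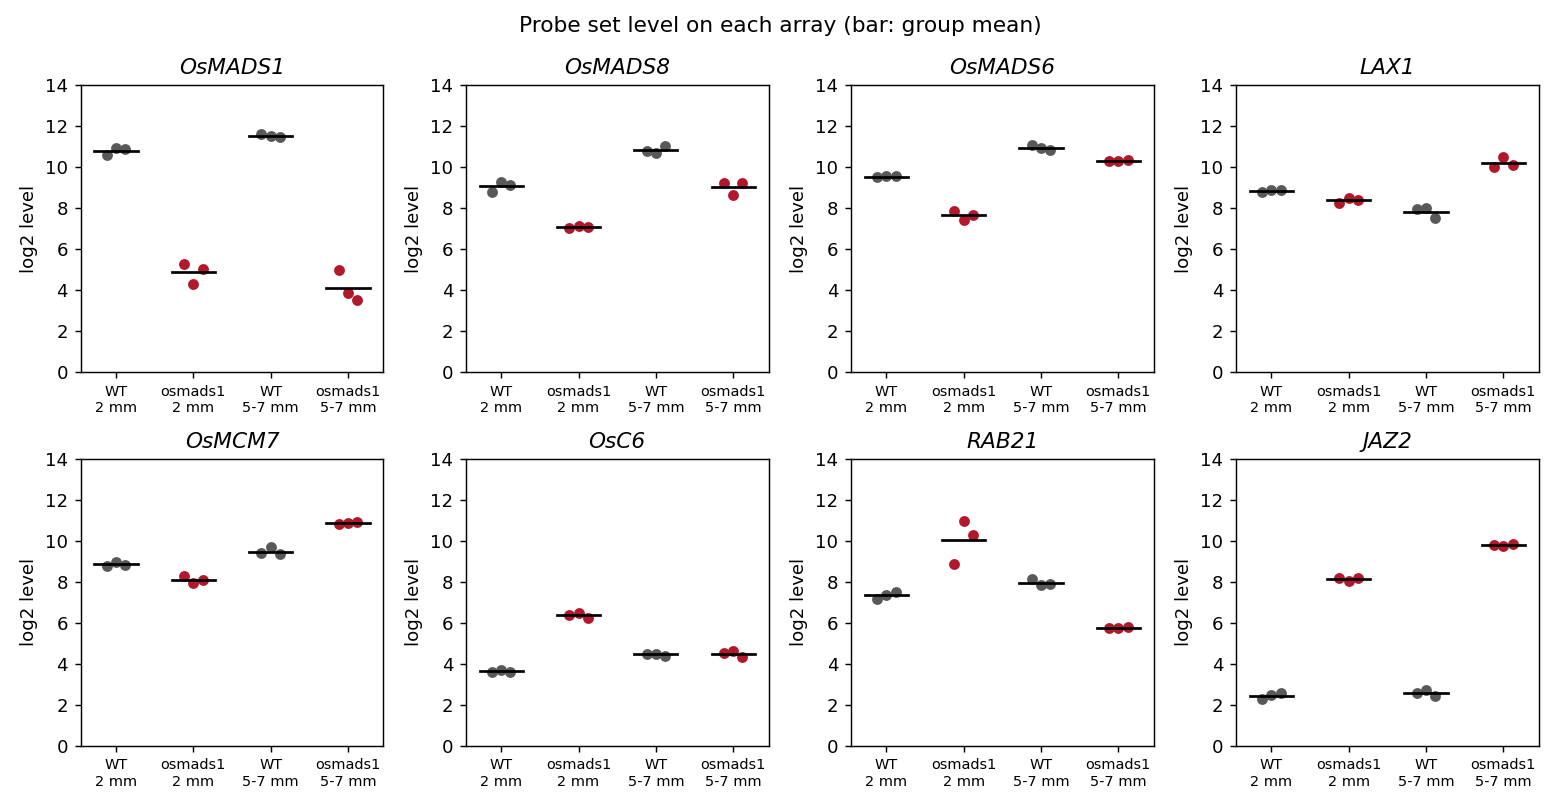
Log2 level of 8 genes on each of the 12 arrays (points) with the group mean (bar), for wild type (grey) and osmads1 (red) at 2 mm and 5-7 mm. OsMADS1 lies between 3.49 and 5.25 on the mutant arrays, and RAB21 and OsMCM7 change the direction of their genotype difference between the lengths.

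More probe sets differed in opposite directions at the 2 lengths than in the same direction. JAZ2 was higher at both lengths, and OsMADS1, OsMADS7, OsMADS8, OsMADS17 and the B class genes were lower at both. At both lengths 283 probe sets were higher and 384 lower in osmads1, against 320.5 and 405.4 for independent lists of these sizes. Opposite directions were called for 2587, of which 1431 were higher at 2 mm and lower at 5-7 mm and 1156 the reverse, against 354.8 and 366.3. All 2587 also passed the interaction test, which follows from opposite calls at both lengths and adds no support. The genotype contrasts share no array, and their correlation across probe sets, which are not independent replicates, was -0.22. At least 4-fold in one direction at both lengths were 16 probe sets. The largest of these differences was that of LOC4331398 on chromosome 3, at least 411-fold and 405-fold higher in osmads1, a gene named here after its values were seen. Its wild-type levels (3.22 and 3.43) lay in the range of reporter controls, so that these are lower limits.

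**Figure D4:**
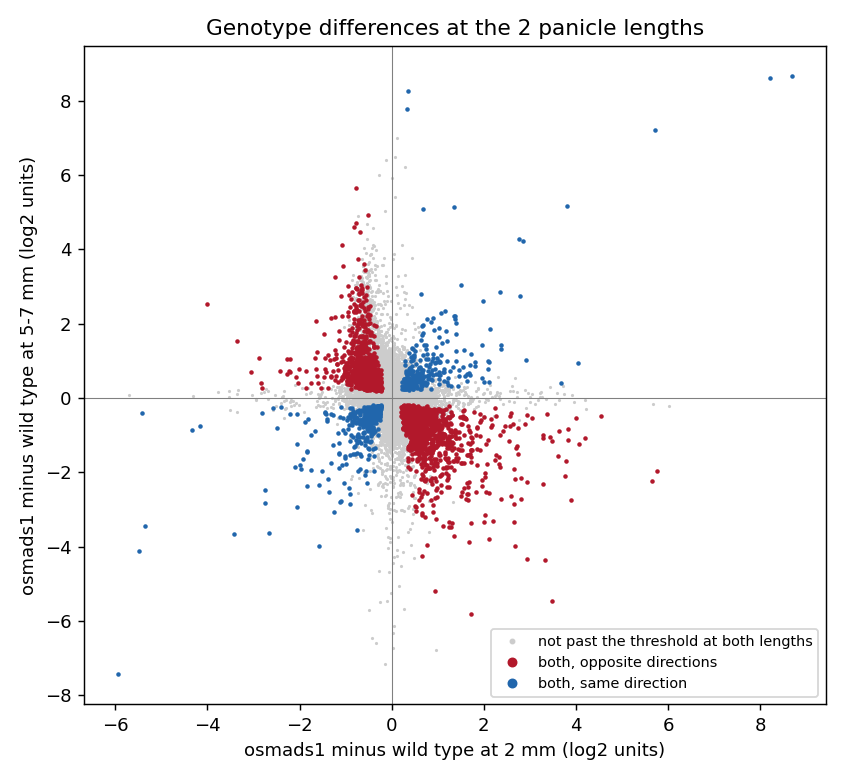
Difference between osmads1 and wild type of each probe set at 2 mm (horizontal) and 5-7 mm (vertical), in log2 units, with probe sets past an adjusted p of 0.05 at both lengths in red (opposite directions, 2587) or blue (same direction, 283 higher and 384 lower). The correlation across probe sets is -0.22.

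Between the lengths, the C class gene OsMADS58 rose in both genotypes. After quantile normalization of all arrays together, OsMADS58 was higher at 5-7 mm than at 2 mm by 2.72 in wild type and 2.25 in osmads1. In wild type OsC3H40 (5.44), the TCP gene PCF5 (2.82) and SPL16 (2.73) rose, and EM (-5.31), OsSWEET15 (-3.64), HSFB2C (-3.64) and GRXC10 (-3.01) fell. In osmads1 OsPCL1 (5.53), OsSAPK9 (3.51) and the zinc transporter gene OsZIP1 (2.57) rose, and HSFC2A (-6.16), RAB16B (-6.13), OsCCA1 (-4.96) and AMY1.3 (-4.83) fell, each past an adjusted p of 0.05 with limma. At 5-7 mm GRXC10 in wild type (2.71) and HSFC2A (3.76), RAB16B (3.65) and AMY1.3 (3.24) in osmads1 read in the range of reporter controls. The sizes of these falls are therefore lower limits. As deposited, 45724 probe sets passed in wild type (42143 higher, 3581 lower) and 45509 in osmads1 (42388 higher, 3121 lower), with the median probe set 0.606 and 0.605 higher. The percent of calls that were higher was 92.2 in wild type and 93.1 in osmads1 as deposited, 24.2 and 24.7 after centring arrays on their medians, and 52.8 and 53.1 after quantile normalization. The array levels look as if the lengths had been normalized apart, in which case stage and normalization cannot be told apart in these counts. Control readings differed between the lengths as well. The control AFFX-Os_18SrRNA_at read 12.75 in osmads1 and 12.69 in wild type at 2 mm, and 7.13 and 7.29 at 5-7 mm. The actin 3' minus 5' difference was 4.59 and 5.11 at 2 mm, and 3.18 and 2.98 at 5-7 mm. A difference in RNA or labelling may thus also lie with length, and quantile normalization may not remove it from the rises and falls above.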

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

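The tests of explanations given here for the 3 patterns were all chosen after the result had been seen, as was the count of probe sets changed in opposite directions, while the counts over other splits of the arrays for all other results were planned.

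The genotype difference differed between the lengths for 12750 probe sets, and 2587 changed in opposite directions. Of 100 drawn relabelings of genotype within lengths, 1, the real one, gave as many as 12750 (highest other 6967) and 1 as many as 2587 (highest other 667). These counts argue against genotype labels that carry no difference at all. A relabeling that mixes genotypes puts the real genotype difference into the spread and so yields fewer calls. Whether the genotype effect differs between lengths, or the groups differ in line or harvest, is not decided by it. For the 667 probe sets changed in the same direction 2 of 100 gave as many, the other with 2587 being the real arrays with genotype labels swapped at one length. For the 6737, 12285, 45724 and 45509 calls of the simple contrasts, 1 of the 10 splits gave as many in each case and the highest other was 0, and 10 splits are too few for a share under 0.05. The same limit holds for the 7 lists at 2 mm (1 of 10, highest other 6). A split that mixed genotypes thus gave 6 lists with 0 probe set calls, so the number of lists hardly sets genotype apart there. For the 2 lists at 5-7 mm 3 of 10 splits gave as many (highest other 2), so chance is not excluded for them. For the 3 lists of the interaction 27 of 100 relabelings gave as many (highest other 7), so chance is not excluded for that count.

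The list shifts that differed between lengths were anther (mean interaction -0.93), cell cycle (0.42) and histone (0.43). With an estimated correlation the adjusted p of each in limma's camera test was 0.874. Of 80 named genes checked, 64 had an interaction past the threshold. Falls relative to 2 mm were RAB16B -5.50, OsC3H37 -5.07, OsC3H40 -4.94, RAB21 -4.87, OsWRKY71 -4.80, OsNAC6 -4.66, AMY1.3 -4.41, BC1L9 -4.37, OsC4 -3.83, HSFC2A -3.79, OsCCA1 -3.27, OsNIP4;1 -3.08, OsC6 -2.70 and DREB1A -2.16. Smaller negative interactions were RAFTIN1 -1.80, CYP703A3 -1.79, petC -1.74, TIP2 -1.72, PORA -1.70, PIN3A -1.68, OsMADS13 -1.65, OsMADS1 -1.49, PSAG -1.41, JAZ10 -1.41, OsMADS22 -1.07, EUI1 -1.06, OsSPL14 -0.97, LOG -0.95, TDL1A -0.80, GID1 -0.78, HSP17.9A -0.72 and JAZ7 -0.57. Positive interactions were cob 3.57, OsPCL1 3.57, OsSWEET15 3.54, EM 3.32, LAX1 2.85, OsSAPK9 2.29, RCABP69 2.22, OsMCM7 2.12, CAB2R 2.11, HSP18.6 1.94, OsMCM6 1.92, OsMCM4 1.89, OsMCM2 1.81, OSH6 1.54, JAZ2 1.497, CRC1 1.31, RFL 1.28, HSFB2C 1.26, OsMADS6 1.23, JAZ8 1.12, OsLG1 1.08 and OSH71 1.04. Smaller ones were KIN8B 0.87, MSP1 0.85, OSH3 0.82, OsMADS17 0.81, LFNR1 0.79, OsETTIN1 0.70, OSH1 0.67, H2B.10 0.57, OsMADS15 0.44 and OsMADS50 0.41. Leaving out single arrays lost the interaction calls of OsMADS1 and TDL1A (adjusted p up to 0.0685 and 0.0866), and gave RAB21 -5.46 without osmads1 replicate 1 of 2 mm and AMY1.3 -3.78 or -5.12 without wild-type replicate 1 or 2 of 5-7 mm. That of JAZ2 compares lower limits, its wild-type levels (2.44 and 2.58) being in the range of reporter controls.

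Opposite genotype differences such as those of RAB21 and OsMCM7 might come from developmental age, from handling or from a separate normalization of the lengths, which array levels point to and the labels do not state. Quantile normalization of the 12 arrays together left the correlation of the 2 genotype differences at -0.218. Both differences lie within a length, where the arrays were nearly equal already. Renormalizing the deposited values could thus change them little, so this test decides little by itself. Array medians of both genotypes lay within 4.098 to 4.134 at 2 mm and 4.931 to 5.004 at 5-7 mm. Normalizing the lengths apart would thus act alike on both genotypes of a length. That argues against it as the source of opposite signs within lengths. Suppose osmads1 were ahead in age at 2 mm and behind at 5-7 mm, the 2 shifts together being less than the step between lengths. Most of the 2587 would then change with stage in one direction in both genotypes. After quantile normalization 30 percent did. Shifts that together exceed the step are not covered, and choosing the 2587 for opposite differences itself lowers this share. It argues at most against the smaller shift as the whole cause, and only if these stage signs hold. Contrasts between lengths may mix stage with normalization. The share over all probe sets, 72.9 percent, is no fair comparison, since opposite genotype differences by themselves set the 2 stage changes apart. In 84.3 percent of the 2587 the wild-type stage change had the sign of the 2 mm genotype difference. That share rests partly on shared wild-type arrays, so that an effect of age stays open. By sign alone, 5 of 10 ABA and dehydration genes were higher in osmads1 at 2 mm and lower at 5-7 mm. RAB25 alone passed the threshold at both. Its 2 mm call (adjusted p = 0.0472 with limma) was lost without any single 2 mm array other than osmads1 replicate 1 (up to 0.194). Leaving out any single osmads1 array of 5-7 mm lost it too (up to 0.0586). The value of 5 just meets the bound of at least 5 for more water stress of osmads1 at 2 mm and wild type at 5-7 mm. List and bound were set after related genes had been seen. The bound stood for a time at more than 5 after the value was known, under which 5 would not meet it. Time and manner of harvest are not in the labels and lie with the groups, so handling stays open beside an effect of OsMADS1 that differs with stage.

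At least 4-fold differences in one direction at both lengths, such as those of JAZ2 and LOC4331398, were seen in 16 probe sets. Independent lists would give 1.13, which argues against chance overlap, although the shared estimate of the spread may make 1.13 too low. Of the 8 genes other than OsMADS1, 1 lies on chromosome 3 with OsMADS1, which argues against linkage to that locus as the cause for most of them. Among the 5 genes with another probe set, 4 had one that changed less than 2-fold or in the other direction at a length, in line with a candidate explanation that a sequence difference between the lines lies under single probe sets, although splice forms and dim probe sets stay open. For LOC4331398 both probe sets rose, by at least 8.20 at each length. It was singled out because all its probe sets changed, so this was no separate test. A sequence difference under 1 probe set alone would not move both, but one under both probe sets was not tested. For JAZ2 and others with a single probe set the explanation was not tested, and an effect of OsMADS1 stays open.

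Outside the tested probe sets, the reporter control probe set RPTR-Os-K01193-1_at was higher in osmads1 at 2 mm by at least 3.70 (at least 13-fold, adjusted p = 4.55e-10 with limma). These are lower limits, since its wild-type level of 2.91 lay in the range of reporter controls. At 5-7 mm the probe set was not higher (interaction -3.69, adjusted p = 4.69e-08). It read 7.02, 6.15 and 6.65 on the osmads1 arrays and 2.83, 3.00 and 2.89 on the wild-type arrays at 2 mm, and from 2.55 to 2.69 on the 6 arrays at 5-7 mm. All 3 osmads1 arrays at 2 mm lay over 1 log2 unit above wild type, which argues against one aberrant array, and 0 of the other reporter probe sets rose, which argues against a general rise of the 64. Such probe sets are made for sequences introduced into plants, and the labels do not say whether the osmads1 panicles of the 2 lengths came from 1 line; different lines were not tested and stay open, which would make the interaction and opposite-direction counts a comparison of lines as well as lengths. No biological explanation was tested.

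Rice control probe sets also read higher in osmads1, at 2 mm AFFX-Os_Cyph_M_at by 0.49, AFFX-Os_Gapdh_5_at by 1.08 and AFFX-Os_Gapdh_M_at by 0.70, and at 5-7 mm AFFX-Os_Actin_M_s_at by 0.35, AFFX-Os_Cyph_3_at by 0.46 and AFFX-Os_Cyph_M_at by 0.43. The 3' minus 5' difference at 2 mm was 2.58 ± 0.059 in osmads1 and 3.58 ± 0.042 in wild type for GAPDH, 4.59 ± 0.089 and 5.11 ± 0.18 for actin, 1.12 ± 0.069 and 1.37 ± 0.19 for cyclophilin, and 0.25 ± 0.068 and 0.51 ± 0.029 for ubiquitin (SD, n = 3). At 5-7 mm it was 2.24 ± 0.44 and 2.095 ± 0.16 for GAPDH and 3.18 ± 0.36 and 2.98 ± 0.041 for actin. Another actin pair at 2 mm gave 5.63 ± 0.11 and 5.76 ± 0.19, with overlapping arrays. Lower in osmads1 at 5-7 mm were AFFX-r2-Bs-thr-5_s_at (-1.51), AFFX-Os-r2-Bs-thr-5_s_at (-0.83), AFFX-ThrX-M_at (-0.75), AFFX-Os-r2-Bs-thr-M_s_at (-0.73), AFFX-ThrX-5_at (-0.52) and RPTR-Os-CVE247372-1_at (-0.47).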

How the results depend on the processing

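Among the named gene values and list shifts compared, no call turned its direction under any alternative. Values that turned sign passed in neither setting, such as the cytokinin list at 5-7 mm (-0.0046, and 0.012 after quantile normalization) and the photosynthesis interaction (-0.022 and 0.030). Stage calls did turn, 14399 of 45724 in wild type and 14113 of 45509 in osmads1 passing in the opposite direction after median centring, and 5379 and 5200 after quantile normalization. Of the 38770 and 38266 centred calls 24.2 and 24.7 percent were higher, against 92.2 and 93.1 as deposited. The alternatives for the opposite-direction count were chosen after seeing the data, and OsMADS1 has 1 probe set, so its other probe sets could not be tried. Counts that moved by over 1.5 times did so as follows, and where the setting tests fewer probe sets or raises the bar that is the cause, otherwise the cause was not tested. Quantile normalization gave 28741 stage calls in wild type and 29471 in osmads1. Keeping probe sets above the median level gave 26234 and 25719, with 1 list at 5-7 mm and 1 for the interaction, and keeping those above the lowest quartile gave 1 list for the interaction. Array weights gave 10552 calls at 2 mm. Requiring 2-fold left 775 at 2 mm, 1954 at 5-7 mm, 3500 interactions, 13632 and 13436 stage calls, 67 in the same and 196 in opposite directions. An adjusted p under 0.01 left 3834, 7627, 8194, 319 in the same and 1291 in opposite directions. One probe set per gene gave 7343 at 5-7 mm, 7952 interactions, and 15632 and 15477 stage calls. With an estimated correlation 0, 0 and 0 lists passed at 2 mm, at 5-7 mm and for the interaction, and with fry 15, 15 and 10.

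Leaving out each array gave 4717 to 6828 calls at 2 mm, 9907 to 12267 at 5-7 mm, 10887 to 12634 interactions, 43991 to 46093 and 43641 to 45625 stage calls in wild type and osmads1, 479 to 653 in the same and 1833 to 2430 in opposite directions. OsMADS1 differed by -6.14 to -5.65 and -7.86 to -7.13. Lists numbered 6 to 7, 1 to 3 and 3 to 4, the 1 at 5-7 mm without wild-type replicate 1. The tally of named gene values covers only part of them, without OsMADS1, the added lists and many interactions. Calls outside it were lost too, such as the interactions of OsMADS1 and TDL1A (adjusted p up to 0.0685 and 0.0866) and that of RAB25 at 2 mm (up to 0.194). OsCCA1 at 5-7 mm lost its call without osmads1 replicate 2 of that length (0.0631). Of the values in the tally, 1629 kept their side of the threshold and 15 lost their call, those of OsMADS50, H2B.10, OsJAG, OSH1 and OsYABBY1 at 2 mm. OsJAG also lost it with its own 6 arrays (adjusted p = 0.0601) and without shrinkage (0.0883), as OsYABBY1 did without shrinkage (0.0554), and OsMADS18 gained one with an intensity trend (0.0272). List calls were lost 4 times and gained 2 times when an array was left out, and above the median level 4 were lost and that of meiosis at 2 mm was gained (0.0308).

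The replicate block gave 6527, 11999 and 12462 calls and changed no list call and no gene call in the tally above. Arrays of the same number in different groups had deviations correlated at -0.0684 to 0.172, 4 of these 12 over 0.1, and the labels name no shared source, so the numbers were not taken to pair arrays. Of the 12 arrays 8 correlated best with their own number, where chance gives 4, and 17 of 216 exchanges of the numbers gave as many, a hint from the data and not the design. Without detection calls, signal over background could not be given, and differences of dim probe sets are limited by it.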

Other observations

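The 3 lists described here were all chosen after related genes had been seen, so their counts describe these arrays and are not independent evidence. DNA replication genes fell in osmads1 at 2 mm and rose at 5-7 mm. Of 26 genes, 24 were lower and 0 higher at 2 mm, and 20 were higher and 0 lower at 5-7 mm. The 2 mm call of OsRFC1 was lost without any single 2 mm array (adjusted p up to 0.157 with limma). Leaving out some single arrays lost those of OsORC1, OsORC2, OsORC4, OsRPA70B and OsRFC4. The 5-7 mm call of OsRPA70C could be lost likewise, and OsORC1 could gain one at 5-7 mm. The DNA polymerase gene OsPOLD1 went from -1.02 ± 0.087 to 0.72 ± 0.087, the chromatin assembly gene FAS2 from -1.03 ± 0.088 to 0.80 ± 0.088, the origin recognition gene OsORC3 from -0.86 ± 0.13 to 1.35 ± 0.13 and the sliding clamp gene OsPCNA from -0.48 ± 0.11 to 1.002 ± 0.11. The list's mean difference was -0.53 at 2 mm and 0.72 at 5-7 mm, and the mean interaction was 1.25. The p of limma's camera test was 1.18e-12, 5.74e-15 and 8.08e-16 for these, and 0.0761, 0.0557 and 0.0499 with an estimated correlation. OsRPA70A (0.21) and OsFEN1A (-0.073) did not pass at either length.

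Of 7 clock genes, 1 was higher and 3 were lower in osmads1 at 2 mm, and 4 were higher and 1 lower at 5-7 mm. OsCCA1, a morning gene of the clock, was at 2 mm 12.9-fold higher in osmads1, while OsPCL1, GI and OsPRR1, which peak later in the day, differed by -3.54 ± 0.11, -1.86 ± 0.069 and -1.15 ± 0.095. At 5-7 mm the same genes differed by 0.42, 0.031, 0.27 and -0.13 (without wild-type replicate 2 of this length the adjusted p was 0.0833 for OsCCA1 and 0.0568 for GI), and OsPRR73 rose by 0.91 ± 0.10. All 7 clock genes had an interaction past the threshold, 5 positive and 2 negative. The time of day of the harvests is not given in the sources used here. As a list they gave a p of 0.13 at 2 mm and 0.0579 at 5-7 mm, and 0.25 and 0.159 with an estimated correlation. The list's interaction had p = 0.0236 with limma's camera test, and p = 0.101 with an estimated correlation.

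ABA and dehydration genes beyond RAB21 and RAB16B were in part higher in osmads1 at 2 mm and lower at 5-7 mm. Of 10 genes, 5 were higher and 0 lower at 2 mm, among them SALT (0.96 ± 0.16) and RAB16C (0.70 ± 0.15). At 5-7 mm 1 was higher, OsP5CS2 (0.78 ± 0.090), and 4 were lower, among them OsABF2 (-1.36 ± 0.13) and RAB25 (-1.27 ± 0.15). The list test gave p = 0.0223 at 2 mm and p = 0.248 at 5-7 mm, and 0.169 and 0.467 with an estimated correlation. The list's mean interaction was -0.63 (p = 0.0167 with limma's camera test, and p = 0.152 with an estimated correlation).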
